A study of Rattus norvegicus with 12 samples.

How the data were processed

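Total RNA was isolated from frozen abdominal mammary gland pairs of female Sprague-Dawley rats, and biotin-labelled RNA made from 8 µg was hybridised to Affymetrix rat arrays, per the labels' protocols. Diets ran from postnatal day 30 to day 64, ovariectomy was on day 50 and 17β-estradiol or vehicle was given for 14 days, per the labels. There were 4 groups of 3 pools, and groups and pool numbers came from the sample titles. One label field names liver while the source field names mammary gland for every sample, and the samples were treated as mammary gland.

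The deposited values were 1 table of 31099 probe sets on 12 arrays. GCOS, the Affymetrix array software, is named in the submitters' processing notes without a version. The summarisation, the normalization and the log base are not given in the sources used here. The deposited values were read as log2 from their range (the widest range of a probe set was 9.85), and every fold change rests on that reading. Each probe set was centred on its median over the arrays (the largest median was 5e-07), so no expression level, background or detection could be used. Array medians lay between -0.0246 and 0.0112, and the values were used without further normalization.

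Probe sets were named from the platform annotation, in which 20826 carried 1 gene, 436 several and 9780 were unnamed here, besides 57 controls. Of the 1-gene probe sets 20758 matched the GRCr8 gene table by gene identifier, with 0 symbols changed. Values of a gene's probe sets were averaged, giving 14217 genes, of which 4525 had several probe sets. Of 662 symbols written into 29 gene lists before the data were examined, older names included, 577 genes were measured.

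The tests fixed before the data were examined assumed levels. Because the values are centred, the filter on dim probe sets, the choice of the probe set with the highest mean and a variance trend on the mean could not be used. They were replaced by no filter, the mean of probe sets and limma's eBayes without a trend. Casein plus E2 pools 2 and 3 were averaged into 1 sample after their agreement was seen. A model of 4 group means was fitted to 11 samples with 7 residual degrees of freedom (limma 3.58.1 in R 4.3.3), and 9 contrasts were tested two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors are standard errors of the fit.

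Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry, and by an exact permutation test of list scores within strata. Calls of list members are given over all genes and adjusted over the list alone. The named genes followed a rule fixed before the data were examined. For E2 in each diet and soy at each E2 level they were the 10 highest and 10 lowest called genes whose groups did not overlap, without LOC or RGD symbols. Where fewer than 5 were called in a direction, the genes of smallest p up to 5 were taken, and the other contrasts took 5 and 5. Up to 4 called members of each list with a camera call and 12 fixed genes were added. The text prints most of these. Fabp1, Ahsg and Cd79b were named after their values were seen.

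The code was tested on simulated data made with known changes. Noise was drawn independently for each gene and array, so the test checks the code and not the power in these pools. For the estradiol average it recovered 91% of 100 genes changed by 1 log2 unit and 97% of those changed by 2, and for the interaction 50% and 88%, among 14217 genes. Alternatives were quantile normalization, median centring, every probe set tested, only the contrast's groups, pool number as a block, array weights, a 1.5-fold minimum and leaving out each array. A fit of 12 separate arrays, the samples fixed before the data were examined, became an alternative once the pair was averaged. Chosen after seeing the data was the spike-in split as a term (sign of the mean of 18 spike-in probe sets), also without casein pool 3. The probe set of largest SD per gene and a variance trend were chosen after seeing the data too. That trend was on the mean of centred values, which is not an expression level.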

Results

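Gene expression was measured in the abdominal mammary glands of female Sprague-Dawley rats that ate casein, a milk protein, or soy protein isolate, a soy preparation that carries isoflavones, from postnatal day 30 to day 64. All rats were ovariectomized on day 50, which removes the main source of estrogen, and received 17β-estradiol (E2) or vehicle for 14 days. The groups were casein, casein plus E2, soy and soy plus E2, each with 3 arrays of pooled RNA. The series asks how soy protein isolate and E2, alone or together, change mammary gene expression. Values were log2 values centred per probe set, so they carry differences between arrays and no expression level, and the number of arrays limits the precision.

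Casein plus E2 pools 2 and 3 were nearly the same array. None of the 31099 probe sets differed by more than 1 log2 unit between them, and the SD of the difference was 0.163, against 0.302 or more in all 65 other pairs of arrays. Over the 1000 most variable probe sets the SD was 0.179, against 0.794 or more in other pairs within a group. Over the 1000 least variable probe sets, chosen for low variation on the other arrays, it was 0.144. Other pairs with 1 of these pools had 0.138 to 0.16. Pairs without them had 0.0966 to 0.1185 and were low by that choice, so they are no measure of ordinary noise for this pair. The pair was counted as 1 sample, so n = 2 for casein plus E2 and n = 3 for the other groups. Nothing in the labels says that pools of one group held different animals, so p-values measure the spread between pools.

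Transcripts of other tissues stood out on some arrays. Casein pool 3 held liver transcripts, with Fabp1, the liver fatty acid binding protein, at 8.01 and Ahsg, a plasma protein, at 7.50, against at most 0.24 and 0.83 on the other arrays. The liver list of 26 genes scored 4.88 there and between -0.72 and -0.16 elsewhere. Skeletal muscle transcripts were high in casein pool 2 (list score 2.82) and soy pool 2 (2.99). Bacterial transcripts added at hybridisation split the arrays into 6 above 0 (all casein pools, casein plus E2 pool 1, soy pool 1 and soy plus E2 pool 2) and 6 below 0, and lymphocyte transcripts split the same way. B-cell receptor component Cd79b lay between -2.34 and -0.92 on the former and between 0.92 and 2.57 on the latter. Centring on the median puts the same number of arrays on each side of 0 for most probe sets, so 6 against 6 is no evidence of 2 batches in itself.

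In casein-fed rats E2 raised milk and estrogen target genes. Wap, the whey acidic milk protein, rose by 5.07 ± 0.93 (log2 fold change ± SE), Wfdc3 by 4.41 ± 0.62, lactoperoxidase Lpo by 4.34 ± 0.34 and fatty acid binding protein Fabp3 by 3.96 ± 0.49. The progesterone receptor gene Pgr, a classical estrogen target, rose by 3.09 ± 0.39, the epidermal growth factor receptor ligand Areg by 3.02 ± 0.59 and Greb1 by 1.53 ± 0.21. Chrdl2 (3.46), Obp3 (3.32), the phosphate transporter gene Slc34a2 (3.31), Clca1 (3.27) and Prr27 (3.10) also rose. Adrb3, the beta-3 adrenergic receptor of fat cells, fell by 2.68 ± 0.55, and the mast cell protease gene Mcpt1l1 fell by 2.53 ± 0.54. Col6a6 fell by 2.38, Cpxm2 by 2.02, Mlip by 1.81, the histamine-forming enzyme gene Hdc by 1.71, Scn7a by 1.67, Kazald1 by 1.60 and Hey2 by 1.56. The mean of 2 probe sets for Greb1 hides a disagreement, with changes of 0.14 and 2.93.

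Of 22 milk and secretory genes 8 rose over all genes tested, and 19 adjusted over the list alone, with a mean change of 2.10 (limma camera adjusted p = 2.5e-13 at the preset correlation, adjusted p = 0.35 with an estimated correlation, fry adjusted p = 0.0237). Of 27 estrogen response genes 5 rose (10 adjusted over the list alone), among them Ramp3 at 1.42 ± 0.18. Of 17 endothelial genes 5 fell (14 adjusted over the list alone), including Cldn5 by 1.24 and Ptprb by 1.15. Of 13 mast cell genes 4 fell (9 lower and 1 higher adjusted over the list alone), including Tpsab1 by 1.51, and of 20 cholesterol synthesis genes 3 fell (15 adjusted over the list alone), Nsdhl by 1.29, Cyp51 by 0.93 and Pmvk by 0.70. Of 20 adipocyte genes 1 fell (8 adjusted over the list alone, mean -1.12), and of 22 luminal epithelium genes 0 passed (7 higher and 1 lower adjusted over the list alone, mean 0.74). Aurka (1.01) and Mcm6 (0.83) were the called genes among 37 proliferation genes. Camera called 15 of 29 lists, 0 with an estimated correlation, and fry called 5. The liver list was 2.04 lower on average and the skeletal muscle list 1.83 lower, with 0 called genes in each. They stand next to the high values in casein pool 3 for liver and casein pools 1 and 2 for muscle.

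In all, 346 of 14217 genes passed for E2 in casein-fed rats (limma, Benjamini-Hochberg adjusted p), 211 higher and 135 lower, and the groups did not overlap in these 346 or in 5662 genes in all, where chance gives 20% of genes. All casein pools were high spike-in arrays and 1 of the 2 casein plus E2 samples was low. With the spike-in split as a term 246 genes passed, 176 of them among the 346, and Wap, Adrb3, Mcpt1l1, Cpxm2, Hdc, Scn7a, Kazald1, Tpsab1, Nsdhl, Cyp51, Aurka and Mcm6 did not pass. Their changes hardly moved, from 5.07 to 5.11 for Wap, from -2.53 to -2.46 for Mcpt1l1 and, in the largest such move, from -1.67 to -1.45 for Scn7a. Csn2 (3.39 ± 1.32, adjusted p = 0.191), Igf1 (-1.64 ± 0.42, adjusted p = 0.0746), Mki67 (0.60 ± 0.27), Ccnd1 (0.51 ± 0.26), Esr1 (-0.26 ± 0.16), Esr2 (-0.03 ± 0.11) and Cdh1 (0.19 ± 0.26) did not pass. Csn2 stood at -5.98 in casein pool 2, against -0.84 and -0.64 in casein pools 1 and 3, and its change was 1.64 without that pool. Wap stood at -4.42 there, and its change was 4.02 without that pool and did not pass. The milk list (-1.73) and the luminal list (-0.79) scored lowest there among the casein pools. The count was 5 without casein plus E2 pool 1, which leaves 1 sample assumed to vary like the other groups, 12 without casein pool 2, 17 without casein pool 1, 68 without soy pool 2, 140 without soy plus E2 pool 2, 157 without casein pool 3, 230 without soy pool 3 and 590 without soy plus E2 pool 3. Lpo was the only one of 37 named calls here that held without each of the 12 arrays in turn.

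In soy-fed rats E2 raised milk and estrogen target genes as well. Wap rose by 6.06 ± 0.83, Areg by 4.62 ± 0.53, Fabp3 by 3.86 ± 0.44, Wfdc3 by 3.62 ± 0.56, Chrdl2 by 3.28 ± 0.41 and Pgr by 2.84 ± 0.35. Spink8 (2.74), Lpo (2.29), Mfap3l (2.11), Ankrd34b (2.10) and the kappa-casein gene Csn3 (1.91) rose as well, and Greb1 rose by 1.37 ± 0.19, with its 2 probe sets at 0.10 and 2.64. Retsat, a retinol saturase, fell by 2.16 ± 0.33, Cpa1 by 2.0 ± 0.25, the mast cell receptor gene Milr1 by 1.56 ± 0.21, the alpha-fetoprotein gene Afp by 1.19 ± 0.12 and Camkmt by 0.67 ± 0.11.

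Of the 22 milk and secretory genes 4 rose over all genes tested and 17 adjusted over the list alone (mean 1.92, camera adjusted p = 1.7e-14, adjusted p = 0.35 with an estimated correlation). No proliferation gene passed over all genes, and 22 of 37 passed adjusted over the list alone (mean 0.54). The luminal and basal lists were higher too, with 0 called genes in each. Adjusted over the list alone, 16 of 22 luminal genes were higher (mean 0.89). Of 18 basal genes 14 were higher and 1 lower (mean 0.62). Soy pool 3 had the lowest luminal (-1.17) and basal (-0.80) scores of all arrays. The skeletal muscle list had a mean of -1.50 and 0 called genes, next to the high value in soy pool 2 (2.99). No adipocyte gene passed over all genes, and 19 of 20 passed lower adjusted over the list alone (mean -1.06), as did 10 of 13 mast cell genes (mean -1.10). Camera called 17 of the 29 lists, 0 with an estimated correlation (smallest adjusted p = 0.345), and fry called 5. In total 31 genes passed, 26 higher and 5 lower, and 2935 had an unadjusted p under 0.05, where chance gives 711. With the spike-in split as a term 73 passed. The count was 0 without soy pool 2 or soy pool 3, 1 without soy plus E2 pool 2, 2 without soy plus E2 pool 1, 4 without soy pool 1, 6 without casein pool 1, 9 without casein plus E2 pool 1 and 760 without soy plus E2 pool 3. Soy plus E2 pool 3 had Wap at 1.22 and Pgr at 0.82, against 3.09 or more and 2.21 or more in the other pools of its group.

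**Figure D1:**
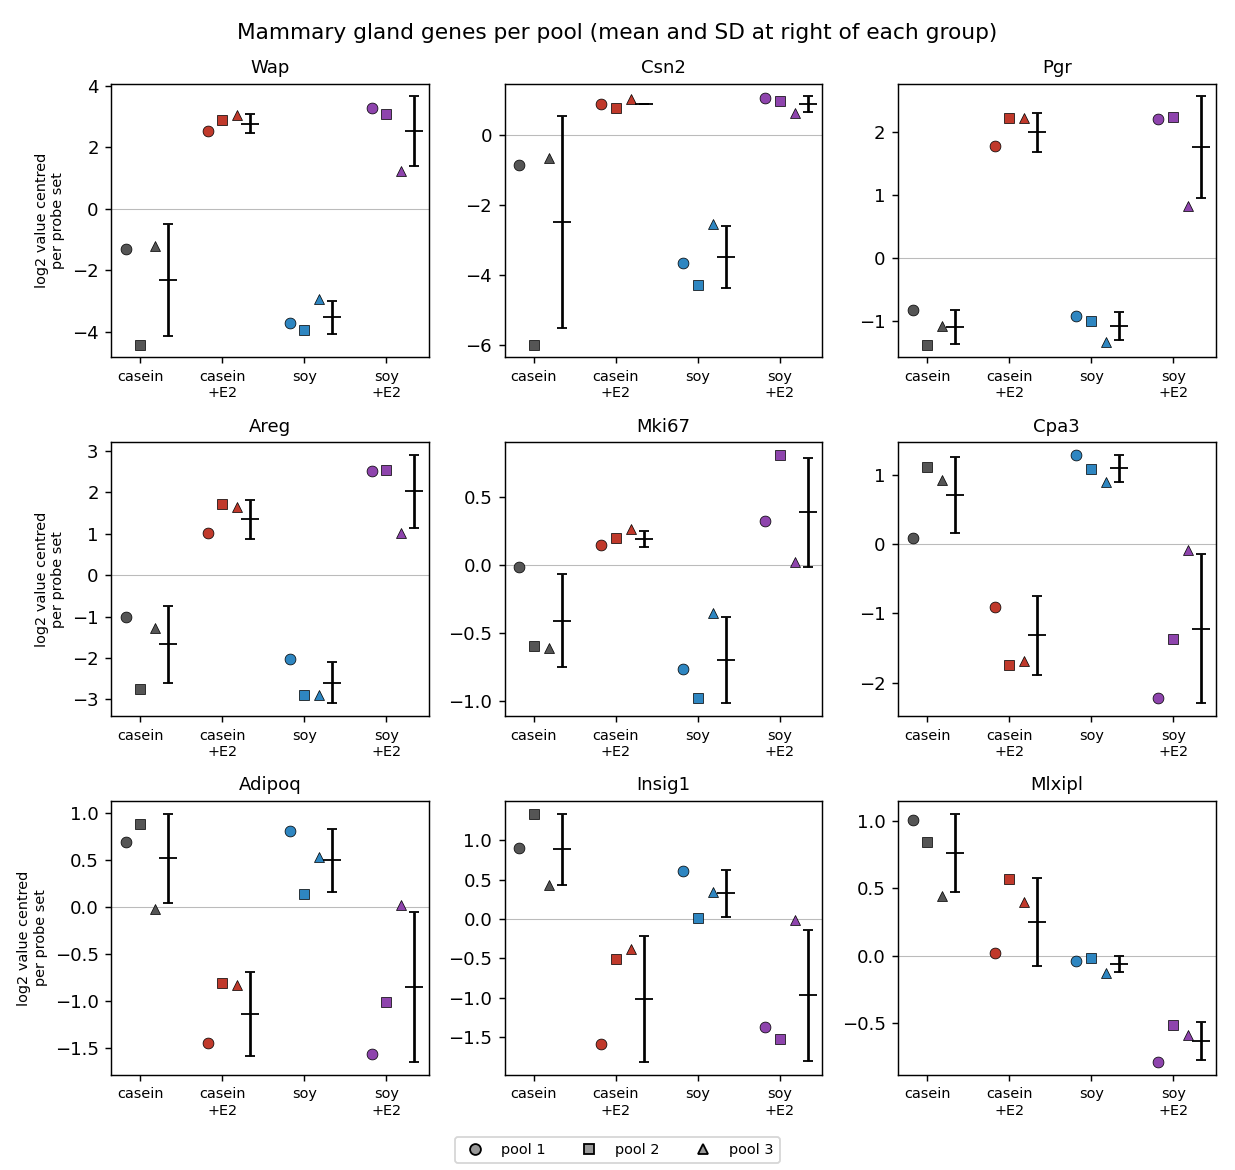
Centred log2 values of 9 genes (y axis) in the 3 pools of each group (x axis, E2 is 17β-estradiol), with the group mean and SD at the right of the points, where casein plus E2 pools 2 and 3 count as 1. Wap lies above 0 in all E2 pools and below 0 in all others, and soy plus E2 pool 3 is the lowest E2 pool for Wap at 1.22.

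Averaged over both diets, E2 raised milk genes and estrogen targets, with Wap at 5.56 ± 0.62, Wfdc3 at 4.01 ± 0.42, Fabp3 at 3.91 ± 0.33, the beta-casein gene Csn2 at 3.88 ± 0.89 and Areg at 3.82 ± 0.40. Of the 22 milk and secretory genes 19 rose (19 adjusted over the list alone), with Glycam1 at 3.78, and the mean change was 2.01 (camera adjusted p = 4.15e-15, adjusted p = 0.30 with an estimated correlation, fry adjusted p = 0.0046). Of 22 luminal epithelium genes 13 rose and 1 fell, with Cd24 at 1.88, the transcription factor gene Gata3 at 1.22 and keratin gene Krt19 at 1.16. Of 18 basal and myoepithelial genes 8 rose, with Krt14 at 1.08 and Krt17 at 0.96. Of 37 proliferation genes 22 rose, with the cell cycle kinase gene Cdk1 at 0.89, Ect2 at 0.87 and Mki67 at 0.84 ± 0.18. Of 27 estrogen response genes 10 rose, with Pgr at 2.96 ± 0.26, Greb1 at 1.45 ± 0.14 and Ramp3 at 0.82 ± 0.12.

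Genes of fat and mast cells and some endothelial genes were lower with E2. RNA was of the whole gland, so changes within cells and changes in cell proportions were not told apart. Of 20 adipocyte genes 13 fell (19 adjusted over the list alone), Adrb3 by 2.12, Pck1 by 1.87, the leptin gene Lep by 1.70 and the adiponectin gene Adipoq by 1.5. Of 13 mast cell genes 9 fell, Mcpt1l1 by 2.42, Cpa3 by 2.17, Fcer1a by 1.89 and Cma1 by 1.67. Of 20 cholesterol synthesis genes 11 fell, with the sterol sensor gene Insig1 lower by 1.60 (-1.60 ± 0.32), Nsdhl by 1.05 and Msmo1 by 0.74. Of 17 endothelial genes 7 fell, including Cldn5 by 0.87, while in soy-fed rats alone 0 of the 17 passed over all genes or adjusted over the list alone (mean -0.14). Of 5 erythroid genes 3 fell, Hbb by 1.26, Alas2 by 1.25 and Ahsp by 0.44. Of 37 extracellular matrix genes 9 fell, including Col15a1 by 1.07, Sparc by 0.94 and Lox by 0.91, and 3 rose, among them Mmp12 at 1.74. Of 24 fatty acid synthesis genes 5 fell, including Pnpla3 by 1.69, and 3 rose, among them Fads2 at 1.05. Igf1 fell by 1.52 ± 0.28 and Ccnd1 rose by 0.62 ± 0.18, while Esr1 (-0.19 ± 0.11), Esr2 (0.03 ± 0.07) and Cdh1 (0.35 ± 0.17) did not pass. Gp2 (-2.40), the chemokine gene Cxcl13 (-2.38) and Grifin (-2.33) fell as well.

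For the E2 average 1741 of 14217 genes passed in limma, 957 higher and 784 lower. In 792 of them, and in 978 genes in all, the 5 samples with E2 did not overlap the 6 without, where chance gives 0.433% of genes. Camera called 16 of the 29 lists, 0 with an estimated correlation (smallest adjusted p = 0.30), and fry called 11. The skeletal muscle list differed by -1.665 and the liver list by -0.97, next to the high values in casein pool 2 and soy pool 2 for muscle and casein pool 3 for liver. In an exact permutation test of list scores within each diet (200 splits, two-sided, adjusted over 29 lists), the milk, estrogen response, luminal, proliferation, mast cell, cholesterol synthesis and erythroid lists had adjusted p = 0.0207, the brown adipocyte and the insulin and insulin-like growth factor lists adjusted p = 0.0322, and the adipocyte list adjusted p = 0.0435. The other 19 lists, among them the basal (adjusted p = 0.0527) and endothelial (adjusted p = 0.0669) lists, did not pass this exact test. The E2 average had r = 0.712 across genes between the 6 high and the 6 low spike-in arrays. The low ones hold no casein pool without E2, so E2 and diet are not balanced there. Within these sets the milk list changed by 1.98 and 2.08, the mast cell list by -1.03 and -1.05 and the adipocyte list by -1.41 and -0.75. The count was 313 without casein plus E2 pool 1, 640 without soy plus E2 pool 2, 642 without soy plus E2 pool 1, 899 without casein pool 2 and 1123 without soy pool 2, and 16 of the 60 named calls held without each array in turn, among them Wap, Pgr, Areg, Cpa3 and Cdk1.

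**Figure D2:**
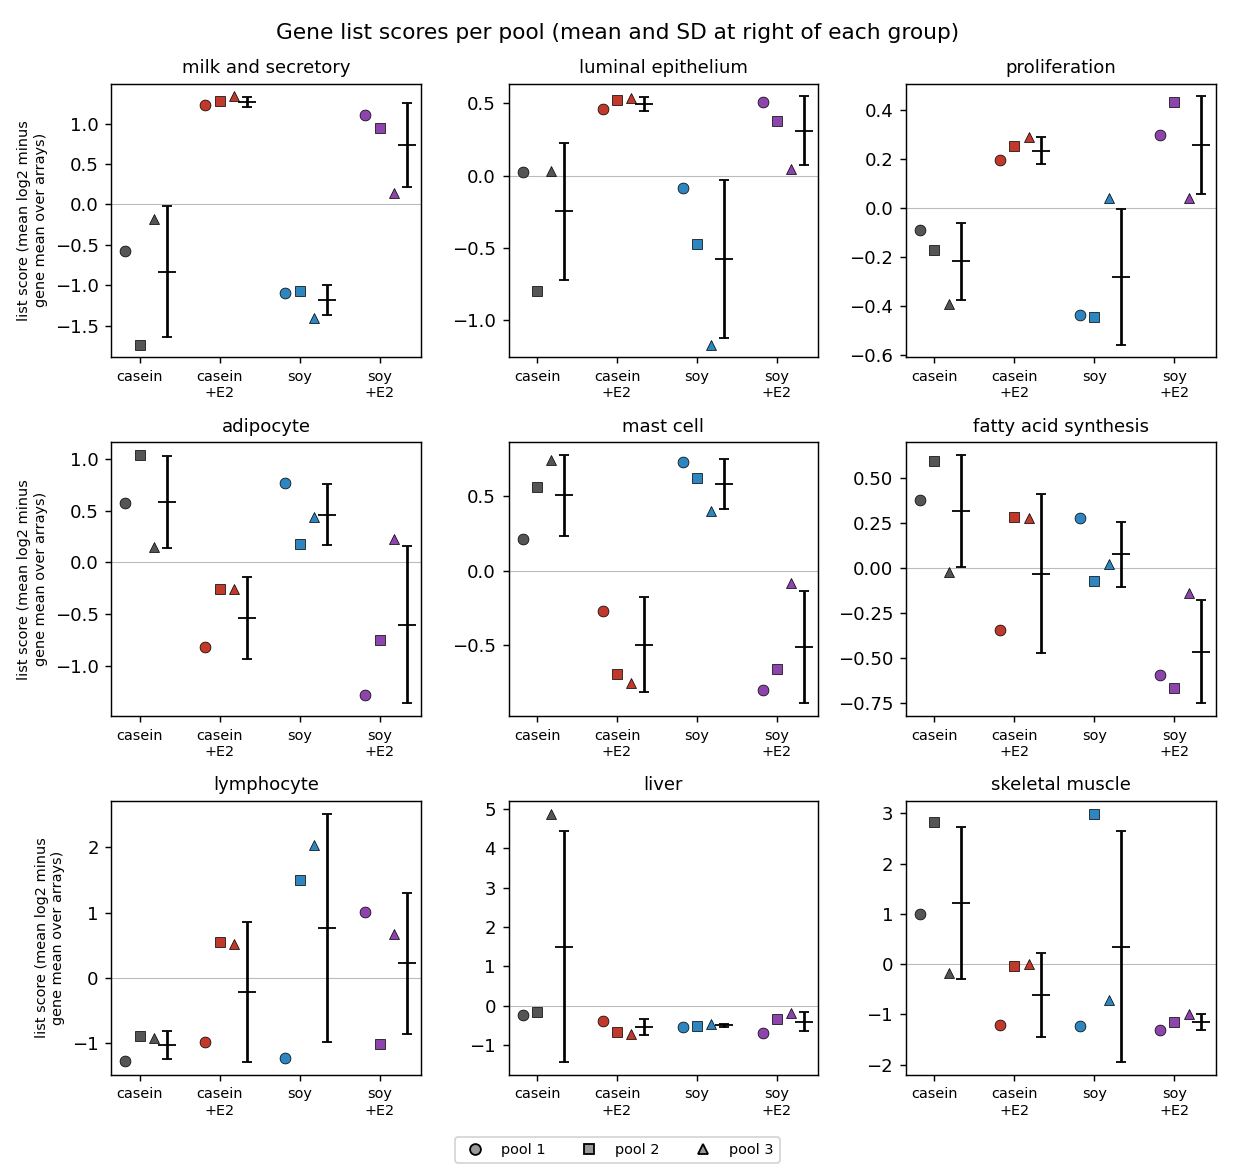
Scores of 9 gene lists (y axis, mean over a list of the log2 value minus the gene's mean over the arrays) in the 3 pools of each group (x axis), with the group mean and SD at the right of the points. The liver list scores 4.88 in casein pool 3, and the lymphocyte list lies above 0 in 6 pools, with soy pool 3 highest at 2.03.

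The difference of the E2 effects between diets, the interaction, asks whether soy changed the response to E2. No gene passed it in limma, 929 had an unadjusted p under 0.05, where chance gives 711, and the smallest adjusted p was 0.141, for Ppif and Zcchc10. E2 changed Ppif, the mitochondrial cyclophilin gene, by 1.30 less in soy-fed rats (-1.30 ± 0.17), Afp by -1.35 ± 0.18, Kcne1 by -1.80 ± 0.26 and Wif1 by -1.55 ± 0.25, and none of these passed. Wap (0.98 ± 1.25), Areg (1.60 ± 0.80), Pgr (-0.25 ± 0.52) and Csn2 (0.99 ± 1.77) had errors too wide to show that the diets were alike. With the spike-in split as a term 1 gene, Ppif, passed. Camera called 11 lists, 0 with an estimated correlation (smallest adjusted p = 0.544), and fry called 0. Across genes the E2 effects in casein-fed and soy-fed rats had r = 0.609 and rho = 0.498, and r was 0.443 without casein pool 2. Simulated unchanged groups gave about 0, but their noise was independent between genes, which fixes that value in advance. It sets no chance level for these pools, and genes are not independent replicates. Of 211 genes raised in casein-fed rats 18 were among the 26 raised in soy-fed rats, where independent lists would share 0.386, and 195 had the same sign there. Of 135 lowered genes 124 had the same sign.

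**Figure D3:**
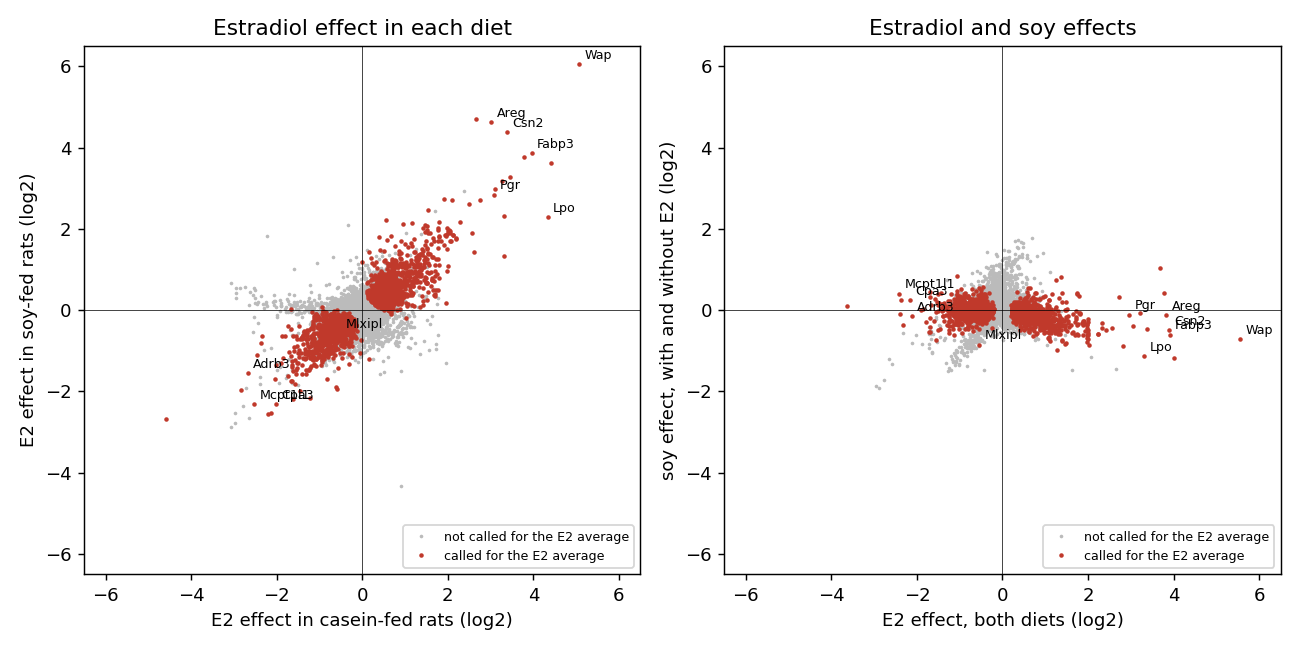
Log2 fold changes of 14217 genes for E2 in casein-fed (x axis) against soy-fed rats (y axis) on the left, and for E2 (x axis) against soy (y axis), each averaged over the other factor, on the right, with genes called for the E2 average in red. The left cloud slopes upward (r = 0.609), which does not show effects of equal size, and the right one shows no slope (r = -0.02).

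Soy without E2 changed no gene past the test. Limma called 0 of 14217 genes, 1472 had an unadjusted p under 0.05, where chance gives 711, and the smallest adjusted p was 0.373. The count was 327 without soy pool 1 and 1588 with array weights (1136 higher and 452 lower). The genes of smallest p were Zfp26 (0.70 ± 0.09), Lrif1 (0.66 ± 0.10), Cdc73 (1.06 ± 0.17), Siglec10 (1.29 ± 0.22) and Giot1 (0.70 ± 0.12) on the higher side. On the lower side they were Xylb (-0.89 ± 0.16), Pln (-0.62 ± 0.12), the hormone gene Fgf21 (-0.58 ± 0.11), Mlxipl (-0.82 ± 0.16), a transcription factor of lipid synthesis, and Apln (-0.68 ± 0.13), none of which passed. The estrogen targets Pgr (0.01 ± 0.35), Greb1 (-0.31 ± 0.19) and Areg (-0.93 ± 0.53) and the milk genes Wap (-1.22 ± 0.83) and Csn2 (-1.0 ± 1.18) did not pass either, nor did Ccnd1 (-0.35 ± 0.23), Mki67 (-0.29 ± 0.24) or Igf1 (-0.14 ± 0.38). In simulated data limma recovered 79% of genes changed by 1 log2 unit and 93% of those changed by 2 in this comparison. The simulated noise was independent between genes and held no differences between pools such as those seen here. These shares therefore do not show that real soy effects of that size would have passed.

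Camera called 13 lists for soy without E2, 0 with an estimated correlation (smallest adjusted p = 0.68), and fry called 0. The lymphocyte list was 1.79 higher on average with 0 of 21 genes called (1 adjusted over the list alone), and it was -0.20 within the high spike-in arrays and 0.34 with the split as a term. The macrophage list was 0.49 higher (0 of 17 called, 9 adjusted over the list alone), the fatty acid synthesis list -0.24 (0 of 24 called, 1 adjusted over the list alone) and the liver list -2.0, next to casein pool 3. All casein pools were high spike-in arrays and soy pools 2 and 3 were low ones. Soy pool 1, without which 327 genes were called, is the soy pool that shares the casein pools' spike-in side.

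Soy in E2-treated rats changed 1 gene, Ppif, which was lower by 1.23 (-1.23 ± 0.12, adjusted p = 0.0324). Kcne1 (-1.58 ± 0.19, adjusted p = 0.076), Adamts19 (-1.29 ± 0.17), Folr1 (-1.06 ± 0.16), Tmem44 (-1.09 ± 0.17), Erich2 (1.15 ± 0.18), the circadian genes Dbp (1.35 ± 0.26) and Per3 (0.70 ± 0.14), Tor3a (0.96 ± 0.19) and the chemokine gene Ccl5 (0.93 ± 0.19) had the next smallest p and did not pass. Pgr (-0.24 ± 0.39), Areg (0.68 ± 0.59), Wap (-0.23 ± 0.93) and Csn2 (-0.01 ± 1.32) did not pass. The endothelial list was 0.39 higher and the fatty acid synthesis list -0.43, with 0 called genes over all genes and 1 fatty acid synthesis gene lower adjusted over the list alone. The milk list was -0.53 with 19 of 22 genes lower, 0 called over all genes and 1 lower adjusted over the list alone (camera adjusted p = 5.1e-05, adjusted p = 0.67 with an estimated correlation). Camera called 8 lists, 0 with an estimated correlation (smallest adjusted p = 0.45), and fry called 0. At an unadjusted p under 0.05 there were 725 genes, where chance gives 711. The count past the test was 3 without soy plus E2 pool 2, 2 without soy pool 1, and 0 without casein pool 1 or 3, casein plus E2 pool 3, soy plus E2 pool 1 or 3, or soy pool 2 or 3. Ppif itself also missed the threshold without casein pool 2 or casein plus E2 pool 1.

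Averaged over E2 treatment, soy changed no gene past the test, and 1005 had an unadjusted p under 0.05, where chance gives 711. The smallest adjusted p was 0.223, for Ppif (-0.58 ± 0.08), Mlxipl (-0.85 ± 0.12), the cholesterol transporter gene Abca1 (-0.45 ± 0.06) and Psme4 (-0.48 ± 0.07). Ccl5 (0.82 ± 0.13), Zfp26 (0.44 ± 0.07), Cdc14a (0.43 ± 0.07), Serpinb9 (0.46 ± 0.08) and Klre1 (0.67 ± 0.12) were next on the higher side. The fatty acid synthesis list was -0.34 on average (-0.35 within the high and -0.47 within the low spike-in arrays, where E2 treatment was not balanced), with 0 of 24 genes called and 1 adjusted over the list alone. Camera called 10 lists, 0 with an estimated correlation (adjusted p = 0.68), fry called 0, and in the exact permutation test every list had an adjusted p of 0.644 or more. The count was 1 without casein plus E2 pool 1 and 1 without soy plus E2 pool 2. The soy effects without and with E2 had r = 0.14 across genes, and the E2 and soy averages r = -0.02, where simulated unchanged groups gave r = -0.11. E2 in casein-fed rats and soy without E2 share the casein pools, and their r of 0.414 compared with 0.447 in simulated unchanged groups, with a covariance of 0.0628 against 0.0299. The simulation gave every group the same spread, while casein pools 2 and 3 had the largest array SDs (0.391 and 0.451, against at most 0.369 elsewhere). The simulated values are therefore approximate, and the larger covariance does not show shared effects.

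Soy plus E2 against casein alone changed 44 genes, 25 higher and 19 lower. Areg rose by 3.70 ± 0.53, Fabp3 by 3.31 ± 0.44, Cxadr by 3.06 ± 0.46, Chrdl2 by 2.91 ± 0.41, Pgr by 2.85 ± 0.35 and Lpo by 2.17 ± 0.31. Cpa1 fell by 2.27 ± 0.25, Retsat by 2.10 ± 0.33, the mast cell tryptase gene Tpsab1 by 1.92 ± 0.27, Dguok by 1.51 ± 0.24, Nsdhl by 1.41 ± 0.23 and Mlxipl by 1.40 ± 0.16. Wap (4.84 ± 0.83, adjusted p = 0.0597) and Greb1 (1.06 ± 0.19, adjusted p = 0.0644) did not pass. Of 24 fatty acid synthesis genes 1 fell (17 adjusted over the list alone, mean -0.78), of 20 cholesterol synthesis genes 2 fell (12 adjusted over the list alone, mean -0.57) and of 22 milk genes 1 rose (15 adjusted over the list alone, mean 1.56). No gene of the adipocyte list passed over all genes, with 19 of 20 lower adjusted over the list alone (mean -1.19). The liver (-1.90) and skeletal muscle (-2.37) lists had 0 called genes, next to casein pool 3 for liver and casein pools 1 and 2 for muscle. Camera called 17 lists, 0 with an estimated correlation (smallest adjusted p = 0.32), and fry called 7. With the spike-in split as a term 9 genes passed, 3 of them among the 44. The count was 0 without casein pool 1, soy pool 2 or soy pool 3, 1 without soy plus E2 pool 1 or 2, 2 without casein pool 3, 3 without casein pool 2, 6 without casein plus E2 pool 1 and 734 without soy plus E2 pool 3.

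Soy without E2 against casein plus E2 changed 272 genes, 69 higher and 203 lower in soy. Wap was lower by 6.29 (-6.29 ± 0.93), Wfdc3 by 5.20 (-5.20 ± 0.62), Fabp3 (-4.51 ± 0.49), Lpo (-4.45 ± 0.34), Areg (-3.95 ± 0.59), Pgr (-3.08 ± 0.39) and Greb1 (-1.85 ± 0.21) were lower too, and so were Cd24 (-2.14) and Gata3 (-1.80). Mcpt1l1 (2.83 ± 0.54), Cpxm2 (2.0 ± 0.40), Milr1 (1.86 ± 0.23), Col6a6 (1.85 ± 0.33) and Pcdh20 (1.53 ± 0.32) were higher. Of 22 milk and secretory genes 10 were lower and of 27 estrogen response genes 5, with list means of -2.45 and -0.49 (20 lower, and 9 lower and 2 higher, adjusted over the list alone). The luminal list scored -1.17 to -0.09 in the soy pools, lowest in soy pool 3, and 0.46 to 0.54 in the casein plus E2 pools. The basal list scored -0.80 to -0.08 and 0.18 to 0.26. Camera called 16 lists, 0 with an estimated correlation (smallest adjusted p = 0.389), and fry called 3. The count was 2 without casein plus E2 pool 1, 33 without soy pool 2, 36 without soy pool 3, 90 without casein pool 1, 479 without soy pool 1 and 540 without soy plus E2 pool 3.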

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

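The tests of the liver transcripts, the lymphocyte transcripts and the response of soy plus E2 pool 3 were chosen after the results were seen, except that of the calls without soy pool 1, which like the tests of other splits was set before its result was seen. Single pools within groups were not tested as outliers.

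Casein pool 3 carried liver transcripts. A hepatic origin predicts that most of the liver list rises together, and 92.3% of its 26 genes lay more than 2 log2 units above the highest other array, with a median gap of 5.41 and no gene shared with another list. Across all genes 155 lay so far above the other arrays there, against at most 1 on any other array. A whole liver sample under a mammary label is argued against by luminal and adipocyte markers, whose mean deficit against casein pools 1 and 2 was 0.0942 (SE 0.0922 over 42 genes, 0.65 for adipocyte and -0.41 for luminal genes, all far below the 2 log2 units it predicts), and the casein diet by the other casein pools, whose highest liver score was -0.155. Liver RNA mixed into this pool is a candidate explanation that stays open, and whether it entered in the tissue or in the tube was not tested.

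Lymphocyte transcripts followed the spike-in split. Of 21 lymphocyte genes 18, or 85.7%, were higher in all 5 low spike-in samples than in all 6 high ones, against 3.59% of all genes, and none is shared with another list. The soy diet was tested within the high spike-in arrays, where the higher soy-fed pool lay at -0.124 from the highest casein-fed pool. These arrays were all low in lymphocyte transcripts (list scores -1.26 to -0.89), so that test cannot decide. On the low side the soy-fed pools scored 0.68 to 2.03, above casein plus E2 pools 2 and 3 (0.55 and 0.52). Against soy as the whole cause, soy pool 1 (-1.225) and soy plus E2 pool 2 (-1.01) scored as low as the casein pools (-1.26 to -0.89). Lymph node tissue in some pools stays open. The lymphocyte list shifted by 2.17 (SE 0.303) between the sides and the macrophage list by 0.06, against a median absolute shift of 0.104 over all genes. Of 219 genes called for the split 215 were higher on the low side. The array medians were already close to 0, so a hybridisation difference that acts on all genes alike would not show in these values. They cannot decide on it, and one limited to some genes stays open. The largest other list shift, of the skeletal muscle list, was 54.2% of the lymphocyte shift but within its own spread (1.18, SE 1.10), and without soy pool 2 the largest was 23.1%. Of the 327 genes called for soy without soy pool 1, 90.8% (94.5% of the 292 higher and 60% of the lower ones) differed in the same direction between the spike-in sides among the E2 pools, where 47.1% of all genes were higher on the low side, and 6 were lymphocyte list genes, so the higher calls may come from the same split, while the share among the lower ones was near that of all genes.

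Soy plus E2 pool 3 had smaller E2 changes. Over the 346 genes called in casein-fed rats, its change from the soy mean had a slope of 0.371 on the E2 effect, above the -0.05 to 0.04 of soy pools against each other, which argues against a soy pool without E2. The slope was 48.7% of the mean of the other pools of the group (0.784 and 0.739), so the same response at a smaller size may apply, from lower exposure or from mixing. The array of this pool also had the smallest SD over all probe sets (0.179, against 0.262 or more on the others). The slope therefore cannot tell a weaker E2 response from a smaller spread of all values on that array. Less epithelium could not be excluded, as the milk list's deficit exceeded the luminal list's by 0.493 (SE 0.127), near the bound of 0.5, and no biological explanation was tested.

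Differences of the E2 effect between diets, tested as an interaction, were called by camera at its preset correlation for 11 lists, with mean differences of 0.38 for basal and myoepithelial genes, 0.24 for cholesterol synthesis, 0.20 for the circadian clock, 0.57 for endothelium, -0.63 for erythroid genes, 0.20 for fatty acid oxidation, 0.21 for immediate early genes, 2.14 for liver, -1.35 for lymphocytes, -0.67 for macrophages and 0.71 for xenobiotic and oxidant response. None was called with an estimated correlation (smallest adjusted p = 0.544) or by fry (smallest adjusted p = 0.504). The liver difference was 0.44 without casein pool 3, the array with liver transcripts. The lymphocyte difference was -0.26 with the spike-in split as a term and no longer called, and it was -0.72 without soy pool 3 and -0.73 without soy plus E2 pool 2, both not called, -2.34 without soy pool 1 and -2.10 without casein plus E2 pool 1. The basal difference was 0.19 without soy pool 3 and 0.24 without soy plus E2 pool 2, and the circadian difference 0.11 without soy pool 3. The cholesterol synthesis difference was 0.03 without casein plus E2 pool 1 and 0.15 without soy plus E2 pool 3, and the fatty acid oxidation difference 0.09 without casein plus E2 pool 1. Leaving out single arrays ended no call for the basal, endothelial, liver and macrophage lists and at least 1 array ended it for each of the others. Among the named genes, groups with and without E2 did not overlap in either diet, in opposite directions, for Xylb (difference 1.13), Per3 (0.79) and Wif1 (-1.55). Chance alone leaves groups of these sizes apart in 20% of genes in casein-fed and 10% in soy-fed rats. The share of all genes with this pattern was not counted. Limma's interaction test did not pass for any of the 3 genes (adjusted p = 0.477, 0.537 and 0.343).

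Among values outside the comparisons, the spike-in mean of casein pool 2 was 1.11, against at most 0.261 on the other arrays. Of 9780 probe sets unnamed here 450 were called for the E2 average.

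Of 100 splits of the samples within diets, drawn from 200 possible, only the real 1 called as many genes for the E2 average, with 1741 against at most 6 in the others. A chance split is an unlikely source of that count, though the other splits mix a strong effect into both groups, which lowers their counts. These splits say nothing about tissue or spike-in differences between pools. For the soy average the real count was 0, which all 100 splits reach whatever the data, and the highest other gave 1, so these splits decide nothing about chance. With 3 pools against 3 the 10 splits are too few for a share under 0.05. The real count and the highest other were 31 and 0 for E2 in soy-fed rats (1 split as large), 44 and 0 for soy plus E2 against casein (1 split as large), and 0 and 0 for soy without E2, where a count of 0 is reached by all 10 splits whatever the data.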

How the results depend on the processing

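Array number and the missing levels limit these results, and signal over background could not be read. Pseudocounts, filters on dim probe sets and the highest-mean probe set could not be run on centred values, and named genes were not recomputed for every probe set. The spike-in split, the largest-SD probe set and the trend were chosen after seeing the data. The 12 separate arrays were the samples fixed beforehand, and averaging the pair was the later choice. The 153 called results of named genes kept their direction under all alternatives run, but the call was lost in 704 and kept in 1132 leave-one-out values, and lost in 297 and kept in 1326 others. The cause of the changes below was not tested, beyond smaller sample numbers.

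Counts of called genes run in this order: E2 in casein-fed rats (346 as reported), soy without E2 (0), E2 in soy-fed rats (31), soy with E2 (1), soy plus E2 against casein (44), soy against E2 (272), interaction (0), E2 average (1741) and soy average (0). Leaving out each array gave 5 to 590, 0 to 327, 0 to 760, 0 to 3, 0 to 734, 2 to 540, 0, 313 to 2334 and 0 to 1. Array weights gave 1408, 1588, 2034, 7, 1176, 2357, 5, 3318 and 24. With 12 separate arrays 1369, 226, 13, 173, 1263, 4 and 2641 were called, with soy alone and the soy average still at 0. Quantile normalization gave 628 for E2 in casein-fed rats, 234 in soy-fed rats (168 higher, or 71.8%, against 83.9%), 6 for soy with E2 (1 higher), 254 for soy plus E2 against casein and 540 for soy against E2. On centred values it gives all arrays a common spread, where their SDs had been 0.179 to 0.451. Testing every probe set gave 1 for soy without E2, 4 for soy with E2 and 2 for the soy average. The largest-SD probe set gave 2 for soy with E2, 25 for soy plus E2 and 176 for soy against E2. A trend gave 56 for E2 in soy-fed rats and 0 for soy with E2, and a 1.5-fold minimum 860 for the E2 average. The spike-in split as a term gave 73 for E2 in soy-fed rats, 9 for soy plus E2 and 1 for the interaction, and without casein pool 3 as well 210 for E2 in casein-fed rats, 69 in soy-fed rats and 4 for soy plus E2. Only the groups compared gave 200, 9 and 1 for E2 in casein-fed rats, in soy-fed rats and soy plus E2.

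Pool number as a replicate block (the merged pair taken as 2) gave 5 for E2 in casein-fed rats, 15 in soy-fed rats, 0 for soy with E2, 0 for soy plus E2, 20 for soy against E2 and 500 for the E2 average. The numbers did not pair the samples: 5 of 18 same-numbered pairs had deviations correlated above 0.1, against 12 of 36 other-numbered pairs. Only 2 of 12 arrays matched best with their own number. Of pairs on the same spike-in side 14 of 24 were above 0.1, and of pairs on different sides 3 of 30. Casein plus E2 pools 2 and 3 entered all these counts as separate arrays.

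Correlations of E2 effects between diets ranged from 0.443 to 0.697 without single arrays, of soy effects from -0.063 to 0.313, of E2 with soy averages from -0.145 to 0.151, and of E2 in casein-fed rats with soy alone from 0.372 to 0.548. Array weights gave 0.516 between diets, -0.147 for the averages (-0.1465) and 0.321 for the last. Quantile normalization gave 0.318 (0.3175) for the last. The spike-in split gave 0.00871 for soy effects, and without casein pool 3 0.75 between diets, 0.134 for the averages and 0.493 for the last.

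Among lists called by camera, those that changed sign were skeletal muscle under array weights (1.25 for soy without E2 and 0.339 for the soy average), lymphocytes for soy plus E2 with the split (-0.205, and -0.15 without casein pool 3), interferon response (-0.0156) and milk genes (0.0666) for soy without E2 with the split and without casein pool 3, and skeletal muscle for soy against E2, from -0.36 to 1.75 without single arrays. Some lists not called also changed sign, among them the lymphocyte list with the split for E2 in casein-fed rats (0.80 to -0.28) and the E2 average (0.13 to -0.41).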

Other observations

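The values below were picked after they were seen. Mlxipl, which encodes a carbohydrate-sensing regulator of lipid synthesis, had soy effects of -0.82 without E2 and -0.88 with E2, and E2 effects of -0.51 in casein-fed and -0.57 in soy-fed rats. Its group means fell in one order, casein, casein plus E2, soy, soy plus E2, and of the 9 contrasts soy plus E2 against casein (-1.40 ± 0.16, adjusted p = 0.0301) and the E2 average (-0.54 ± 0.12, adjusted p = 0.025) passed in limma. The former did not pass with the spike-in split as a term, nor without casein pool 1 or 2, soy pool 2 or 3, or soy plus E2 pool 1 or 2, with values from -1.55 to -1.27 without single arrays. All 24 genes of the fatty acid synthesis list were lower with soy on average (mean -0.34, camera adjusted p = 5.2e-08, adjusted p = 0.68 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. The exact permutation test of list scores gave adjusted p = 0.644 for this list.

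Afp had an E2 effect of 0.15 in casein-fed and -1.19 in soy-fed rats, and Ppif 1.43 and 0.13. The second value for Afp and the first for Ppif passed, and neither interaction passed in limma (adjusted p = 0.15 and 0.141). Ucp1, the uncoupling protein of brown fat, stood at 1.94 in soy pool 1 and at 0.24 or less on the other arrays.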
